A study of Mus musculus with 6 samples.

How the data were processed

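Liver mRNA of male C57BL/6J mice on a high-fat diet (HFD) or the same diet with Bangpungtongseong-san extract (BT) was sequenced from TruSeq libraries, per the labels' protocols, and 3 libraries per diet were analysed. The deposited table gives gene expression as FPKM for 23474 Ensembl mouse gene identifiers, 1 column per library. The submitters' processing notes name CASAVA 1.8.2, STAR 2.4.0 and Cufflinks 2.1.1, with no role or order. The genome build, the annotation release and any strand setting are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. All columns were used, and no 2 libraries held identical values.

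Gene names, positions, transcript lengths and GC contents were taken from GENCODE M21 (GRCm38), which named 22671 identifiers and left 803 unnamed. Coordinates are 1-based and belong to that build, which may not be the one the authors used. No counts came with the values. In genes with 1 annotated transcript over 1000 bases, FPKM times length in kilobases has a lowest cluster, which is what 1 fragment is worth. The median of the values between 0.03 and 0.1 was taken for it. This gave 13.8 to 15.8 M fragments per library (15.8, 13.8 and 15.6 for HFD and 14.4, 15.1 and 14.0 for BT). The estimate is rough, since the fixed window bounds it and corrections for fragment length are ignored. FPKM sums ran from 783151 to 930139. Low genes carry the largest counting error. Alb and mt-Co1 are listed at 0 in HFD replicate 3 and at 22791.1 to 27895.3 and 44333.9 to 53658.8 FPKM in the other 5 libraries. A 0 can thus be a failed estimate, and no absence was read from one. Gnmt, Hpd, Lcat and Lpin2 are listed at 0 in all 6 libraries.

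Values were tested as log2(FPKM + 1) for the 10476 genes with a mean of at least 1 FPKM. limma 3.58.1 in R 4.3.3 was used (lmFit, then eBayes with a trend of variance on mean), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. All adjusted p-values come from these fits or from limma's list tests. Residual degrees of freedom were 4. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.1, so none is given. Changes are BT minus HFD. Errors of levels are SD over 3 libraries, and those of log2 changes are limma's SE. On simulated data with the real means and limma's moderated variances, 200 of 10476 genes were changed by 1 or 2 on the log2 scale. Of these 96% to 100% were recovered with 4.8% false calls, and 0 genes were called when nothing was changed. The simulated genes were independent, with no length or GC trend between libraries, so these rates may not hold for the real calls.

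Before the data were examined, 48 gene lists were fixed for lipid, glucose, bile acid, xenobiotic and stress pathways, the clock, liver cell types and possible other tissues, sex bias, ribosomal proteins and oxidative phosphorylation. Lists were compared with other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 47 lists with at least 2 members tested. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the 4 residual degrees of freedom, which leaves it little power here. The rule for named genes took the 8 largest rises and 8 largest falls among called genes without overlap, the fixed panel, and the 2 members of each list with the smallest p, or 4 where the list passed camera. Names of predicted or unnamed genes were skipped. The rule gave 135 genes, and 57 more were named after their values were seen, most of them further called members of a list. The results of some genes were withheld and are left out of the text and figures, while counts include them.

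Genes whose exons share bases with another gene are uncertain, since no strand setting is given. Other exons cover at least 25% of the exon bases of 11 of the 192 genes taken by the rule or added to it, among them Apoc2, Nr1i3, Tagln, Ugt1a6b, Jund, Scand1, Rpl13a, Sds, Tapbp and Fdps. Values of genes with close paralogs or pseudogenes are also uncertain, and the text marks only some of them.

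Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM, rescaling to TPM (each library to the same sum), median-of-ratios scaling, quantile normalization, no variance trend, robust empirical Bayes, array weights, a replicate block, and leaving out each library. Chosen after seeing the data were removal of each library's trend on transcript length and GC content (natural splines with 5 degrees of freedom), genes with an annotated transcript only, and the zeros of Alb and mt-Co1 as missing. Lists were also set against 10000 random lists of genes matched to each member among its 100 nearest genes in transcript length, GC content and mean expression. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.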

Results

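Liver mRNA was measured by sequencing in male C57BL/6J mice. A high-fat diet (HFD) was compared with the same diet containing 1.5% (w/w) of an extract of Bangpungtongseong-san (BT), an oriental herbal medicine studied against fatty liver disease. The study divided 20 mice into 2 groups of 10, started the diets at 5 weeks of age and fed them for 12 weeks, and its stated interest was mRNA linked to lipid and glucose metabolism. 3 HFD libraries and 3 BT libraries from livers of 17-week-old mice were analysed. The labels do not say whether a library is 1 mouse or a pool, so p-values measure the spread between these libraries. Expression was in FPKM (fragments scaled by transcript length and by mapped fragments) for 23474 genes. The smallest values put the depth at 13.8 to 15.8 M fragments per library, a rough estimate that depends on the window of values used. The library codes in the labels carry one letter in all HFD libraries and another in all BT libraries, so a difference between library sets cannot be told apart from diet.

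Between the diets 1398 of 10476 genes tested (13.3%) differed: 630 were higher and 768 lower with BT. Of these, 55 rose and 113 fell by at least 1 on the log2(FPKM + 1) scale, which understates the change of low genes. The balance between the directions depended on the setting: 448 higher and 884 lower with median-of-ratios scaling, 614 and 557 with each library rescaled to the same sum (TPM), and 855 and 681 without HFD replicate 3. The 3 BT values did not overlap the 3 HFD values in 1396 of the called genes, and in 39.3% of all genes tested, against 10% by chance. The first principal component held 51.8% of the variance and separated the diets, with scores of -30.9 to -12.1 for HFD and 17.9 to 22.4 for BT. The count of changed genes was 173 without BT replicate 1, 324 without BT replicate 2, 589 without BT replicate 3 and 621 without HFD replicate 2. Of 142 named genes past the threshold, 26 also passed in all 6 fits that left out 1 library. Without BT replicate 1, 114 did not pass. BT libraries were more alike than HFD libraries, with SDs of the log2 difference between 2 libraries of 0.237 to 0.311 against 0.383 to 0.411. On the first component BT replicate 1 scored 22.4, against 17.9 and 19.9 for the other BT libraries. A call lost without it is thus no sign that this library stood apart.

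The largest rises included Foxn3, a forkhead transcription factor (chromosome 12, 99190078 to 99563582), from 3.13 ± 2.01 to 30.7 ± 18.5 FPKM (SD, n = 3 each), a log2 change of 2.80 ± 0.52 (SE, adjusted p = 0.0157). Serpina1e, a member of the alpha-1-antitrypsin family, rose by 2.15 ± 0.56 (adjusted p = 0.0414), and Gbp11, a guanylate-binding protein gene annotated as a polymorphic pseudogene, by 2.13 ± 0.31 (adjusted p = 0.00826). Cish, an inhibitor of cytokine signalling, rose by 1.71, Ece1, the endothelin-converting enzyme, by 1.68, and Cyp2c54, a cytochrome P450, by 1.68. A1cf, a cofactor of apolipoprotein B mRNA editing, rose by 1.61 and Clec2h, a C-type lectin gene, by 1.42. The largest fall was that of Mup9, a major urinary protein gene, from 3323 ± 1930 to 104 ± 38.1 FPKM (-4.88 ± 0.46, adjusted p = 0.00187). Its near-identical paralogs make this value uncertain, and the same holds to a lesser degree for Serpina1e, Gbp11, Cyp2c54 and Cyp2b9. The fall of Mup9 was not shared by its family: the 19 Mup genes tested had a median change of 0.53, with 1 lower and none higher. Scand1 (chromosome 2, 156311847 to 156312704) fell from 16.7 ± 5.97 to 0.470 ± 0.324 FPKM (-3.56 ± 0.24, adjusted p = 0.00114). Exons of Cnbd2 on the opposite strand cover 40.4% of its exon bases, which also makes it uncertain. Ly6d changed by -2.76, the histone gene H2afj by -2.14 and Cyp2b9 by -2.04, and Wfdc2 fell from 29.6 ± 15.5 to 6.09 ± 2.15 FPKM. Gdf15, a circulating stress-responsive factor, changed by -1.99 and Fgf21, a metabolic hormone of the liver, by -1.87. Gbp11, Mup9, Scand1, H2afj, Gdf15 and Fgf21 passed in all 6 fits that left out 1 library. The other 10 genes did not, with a highest adjusted p between 0.0572 and 0.127. Foxn3 missed the threshold without HFD replicate 2 and without BT replicate 2, and the other 9 missed it without BT replicate 1, some of them without other libraries as well.

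The panel of lipid and glucose genes fixed beforehand had 4 members lower and none higher among 21 tested (2 higher and 5 lower adjusted over the list alone). Fgf21 (chromosome 7, 45613886 to 45615490) fell from 19.7 ± 3.87 to 4.77 ± 1.75 FPKM (SD, n = 3 each), 4.14-fold (adjusted p = 0.00612). Scd1, the desaturase that makes monounsaturated fatty acids (chromosome 19, 44394455 to 44407879), fell from 1765 ± 462 to 904 ± 153 FPKM (-0.94 ± 0.21, adjusted p = 0.0282). Cyp8b1, which directs bile acid synthesis toward cholic acid (chromosome 9, 121914356 to 121916305), fell from 531 ± 45.9 to 389 ± 20.5 FPKM (-0.44 ± 0.11, adjusted p = 0.0351). These 3 spans are those of whole protein-coding genes in GENCODE M21 (GRCm38). Fgf21 passed in all 6 fits that left out 1 library. Scd1 and Cyp8b1 did not, without BT replicate 1 among others (highest adjusted p 0.111 and 0.129). Scd1 also missed the threshold once each library's length and GC trend was removed (-0.81). The other 17 members did not pass. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 83.8 ± 21.7 and 132 ± 23.2 FPKM (0.67 ± 0.21, adjusted p = 0.0634), and Fasn, fatty acid synthase, at 73.5 ± 24.4 and 43.5 ± 4.21 FPKM (-0.69 ± 0.22, adjusted p = 0.0676). With a replicate block both passed (adjusted p = 0.0269 and 0.0297), and Fasn also passed without HFD replicate 1 (-0.95). Srebf1, a lipogenic transcription factor, differed by 0.63 (adjusted p = 0.0764), and passed with a replicate block, on rescaling to TPM (0.72) and with the length and GC trend removed (0.83). Ppara and Cpt1a differed by 0.34 and 0.24, and Cidec, Cidea, Pck1, Pklr and G6pc by -0.41, 0.44, -0.24, 0.31 and -0.27. Acaca, Pparg, Cd36 and Cyp4a14 differed by -0.14, 0.08, -0.06 and 0.02. The adjusted p of these 11 genes was 0.155 to 0.926, and of them only Cidea passed in another setting (0.79 without HFD replicate 1). Cyp2b10 lay below the filter, at a mean of 0.7 FPKM.

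**Figure D1:**
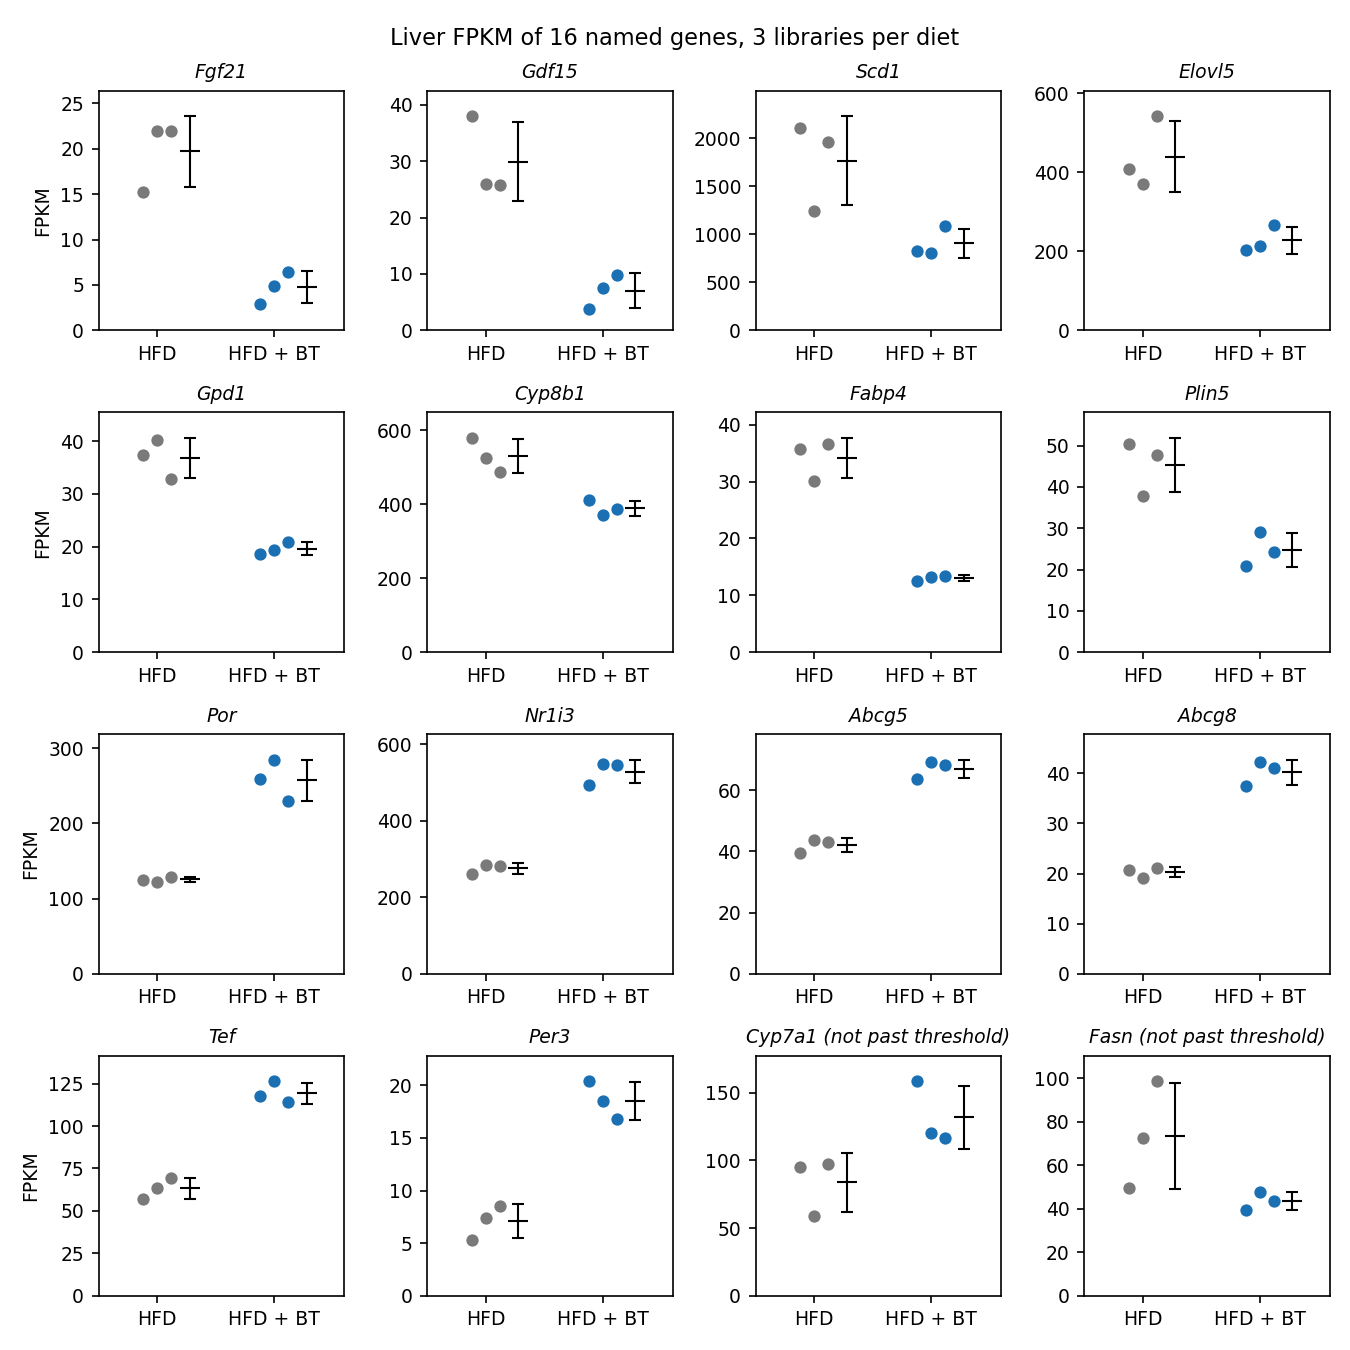
FPKM of 16 named genes on linear axes from 0, with 1 point per library (grey HFD, blue HFD with BT) and the mean ± SD of 3 libraries as bars. The BT values of Fgf21 lie between 2.95 and 6.45, all below the HFD values of 15.24 to 21.99, and those of Por lie between 229.8 and 284.09, all above 122.49 to 129.34.

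In fatty acid synthesis 6 of 16 genes tested fell and 1 rose (7 and 4 adjusted over the list alone). Elovl5, a fatty acid elongase, went from 440 ± 90.4 to 228 ± 33.7 FPKM (-0.94 ± 0.17, adjusted p = 0.0144). Scd1, Acacb, Fads1, Me1 and the citrate carrier gene Slc25a1 were also lower, and Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, was higher by 0.42. In cholesterol synthesis 4 of 24 fell and 1 rose (6 and 1 adjusted over the list alone), among them Fdps (-0.99), Nsdhl (-0.58), Pmvk (-0.62) and Hmgcs1 (-0.73) as lower and Stard4, a sterol transporter gene, as higher (0.50). Among cholesterol efflux genes and LXR targets, the partners Abcg5 and Abcg8, which export sterols into bile, rose by 0.66 ± 0.10 (adjusted p = 0.00828) and 0.95 ± 0.10 (adjusted p = 0.00306). Pltp, a phospholipid transfer protein, fell by 0.81, so 2 of 12 members were higher and 1 lower (4 and 1 adjusted over the list alone). In triglyceride synthesis 2 of 13 fell (3 adjusted over the list alone), Gpd1 (-0.87 ± 0.11, adjusted p = 0.00629) and Agpat2 (-0.44). In these 4 lists Abcg5, Abcg8 and Gpd1 passed in all 6 fits that left out 1 library. The others named missed the threshold without BT replicate 1, with a highest adjusted p between 0.0605 and 0.184.

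Lipid droplet and PPARG-linked genes had 4 of 18 lower and none higher (7 and 0 adjusted over the list alone), with a median change of -0.36 and 16 members negative. The list was lower than other genes by camera with a preset correlation (adjusted p = 0.000101), and adjusted p = 0.667 with an estimated correlation. Fabp4, a fatty acid-binding protein, fell from 34.2 ± 3.49 to 13.1 ± 0.541 FPKM (-1.32 ± 0.11, adjusted p = 0.00127). The droplet coat gene Plin5 fell by 0.85, the liver fatty acid-binding protein gene Fabp1 by 0.71 and G0s2, an inhibitor of lipolysis, by 1.04. In lipolysis and lipoprotein handling 5 of 22 were lower and 2 higher (6 and 3 adjusted over the list alone). The lower genes were Apoc2 (-1.19 ± 0.16, adjusted p = 0.00676), Apoc3 (-0.98), Apoa2 (-0.89), Angptl4 (-0.72) and Angptl8 (-1.22), and the higher ones the carboxylesterases Ces1d (0.72) and Ces1g (0.44). Exons of a neighbouring gene model cover 79.5% of the exon bases of Apoc2. In mitochondrial fatty acid oxidation 3 of 21 fell and none rose (3 and 0 adjusted over the list alone): Eci1 (-0.50), Pdk4 (-0.90) and Acot2 (-0.70). In peroxisomal oxidation and microsomal omega-oxidation 3 of 26 rose and 3 fell (4 and 3 adjusted over the list alone), Slc27a2 by 0.56, Acot3 by 0.73 and Cyp4a12a by 0.82 against Acot4 (-1.28), Acaa1b (-0.56) and Fgf21. Of 6 ketone body genes none passed, also adjusted over the list alone. Slc16a1 differed by -0.55 (adjusted p = 0.0673) and Bdh1 by 0.10 (adjusted p = 0.555). Fabp4, Apoc2, Acot4 and Fgf21 passed in all 6 fits that left out 1 library. The others named here as past the threshold missed it without BT replicate 1, with a highest adjusted p between 0.0543 and 0.157.

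In glycolysis and glucose uptake 2 of 20 fell, among them the fructokinase gene Khk (-0.51), and Slc2a1 rose by 0.54 (2 lower and 1 higher adjusted over the list alone). In gluconeogenesis 1 of 16 rose, Got2 (0.41), and 1 fell, Sds (-0.74), the same counts as adjusted over the list alone. In glycogen metabolism 3 of 12 rose and none fell (3 and 1 adjusted over the list alone), among them Pgm1 (0.55 ± 0.10, adjusted p = 0.0148) and Phka2 (0.69). In insulin signalling 1 of 16 rose, Akt1 (0.36), and 1 fell, Trib3 (-0.69), against 2 and 2 adjusted over the list alone. All genes named here missed the threshold without BT replicate 1, with a highest adjusted p between 0.0687 and 0.15.

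Bile acid synthesis had 1 of 17 members higher, the steroid reductase gene Akr1d1 (0.58), and 1 lower, Cyp8b1 (2 and 2 adjusted over the list alone). Among 11 bile acid transport genes, Abcc2 (0.98) and Slco2b1 (0.36) rose and Abcb11, the bile salt export pump (-0.75), and Abcc3 (-0.48) fell (4 and 2 adjusted over the list alone). Of 19 targets of the xenobiotic receptors CAR and PXR, 8 rose and 2 fell (11 and 4 adjusted over the list alone). By camera the list missed the threshold (adjusted p = 0.0664, median 0.55, and adjusted p = 0.667 with an estimated correlation). By fry it passed as higher (adjusted p = 0.0475). Por, the electron donor of microsomal cytochromes P450, rose from 126 ± 3.47 to 258 ± 27.2 FPKM (1.03 ± 0.11, adjusted p = 0.00306). Nr1i3, which encodes CAR, rose from 275 ± 13.3 to 528 ± 30.8 FPKM (0.94 ± 0.10, adjusted p = 0.00351), although exons of Tomm40l and others cover 74.9% of its exon bases. Cyp2a5, Cyp3a13, Cyp2c54, Cyp2c50, Cyp2c37 and Alas1 rose by 0.56 to 1.68, while Cyp2b9 (-2.04) and Gstm3 (-1.79) fell. Among 7 AHR targets Cyp1a2 rose by 0.77 (1 higher adjusted over the list alone) and Ugt1a6b differed by 0.25 (adjusted p = 0.179). NRF2 targets and glutathione metabolism had 5 of 25 members lower and 1 higher (8 and 1 adjusted over the list alone), with a median of -0.31. The list was lower by camera (adjusted p = 0.000408), and adjusted p = 0.667 with an estimated correlation. The glutathione transferases Gstm1 (-1.05), Gstm2 (-1.17), Gstm3 and Gstm6 (-0.63), which are paralogs, and Gpx4 (-0.96) fell, whereas Osgin1, an oxidative stress-induced growth inhibitor gene, rose by 0.92 ± 0.12 (adjusted p = 0.00644). In amino acid breakdown and the urea cycle 1 of 22 rose and 1 fell, Sds, the same counts as adjusted over the list alone. Por, Nr1i3, Gstm2, Gstm3, Gpx4 and Osgin1 passed in all 6 fits that left out 1 library. The others past the threshold here missed it without BT replicate 1, with a highest adjusted p between 0.057 and 0.141.

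Of 13 genes of the integrated stress response 6 fell and none rose (8 and 0 adjusted over the list alone), with a median of -0.55. The list passed camera at adjusted p = 0.000101, and adjusted p = 0.667 with an estimated correlation. Gdf15 fell from 29.9 ± 6.95 to 7.07 ± 3.03 FPKM (-1.99 ± 0.28, adjusted p = 0.00802), Fgf21 by 1.87, Ddit3, which encodes the factor CHOP, by 0.76, Trib3 by 0.69, Nupr1 by 1.09 and Ddit4 by 0.81. Endoplasmic reticulum chaperones had 1 of 19 members higher and none lower, in all genes and adjusted over the list alone. This was Xbp1, a transcription factor of the unfolded protein response (0.75 ± 0.12, adjusted p = 0.0111), and Hsp90b1 differed by 0.67 (adjusted p = 0.0506). In the heat shock response 4 of 11 fell and none rose (5 and 0 adjusted over the list alone): Hspa1b (-1.23), Hspe1 (-0.69), Hspb1 (-1.25) and Bag3 (-0.53). The list did not pass camera (adjusted p = 0.0517). Immediate early genes, which respond within minutes to stimuli and to tissue handling, had 3 of 15 members lower and none higher, in all genes and adjusted over the list alone, with a median of -0.77. By camera adjusted p was 0.00119, and adjusted p = 0.667 with an estimated correlation. Jund fell by 1.56 ± 0.11 (adjusted p = 0.00114), Jun by 1.22 and Klf2 by 0.62, and Zfp36 differed by -0.90 (adjusted p = 0.0746). An antisense gene model covers 52.6% of the exon bases of Jund. Gdf15, Fgf21 and Jund passed in all 6 fits that left out 1 library. The others past the threshold here missed it without BT replicate 1, with a highest adjusted p between 0.0563 and 0.131.

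Circadian clock genes had 7 of 16 members higher and 1 lower, in all genes and adjusted over the list alone, with a median of 0.47. As a list they passed camera at adjusted p = 0.00241, and adjusted p = 0.667 with an estimated correlation. That correlation was -0.001, below the preset value, so the higher adjusted p does not come from correlation between members. Tef rose from 63.4 ± 6.13 to 119 ± 6.19 FPKM (0.91 ± 0.11, adjusted p = 0.00528), Per3 by 1.29 ± 0.16 and Cry2 by 0.91. Per2 (0.96), Ciart (0.84) and Nr1d2 (0.52) also rose, and Nr1d1, a repressor of the clock, fell by 0.66 (adjusted p = 0.0316). Arntl and Npas2, which act in the opposite phase, lay below the filter and were not tested. Arntl was at 1.4, 0.54 and 1.61 FPKM in the HFD libraries and at 0.6, 0.4 and 0.76 in the BT libraries, which overlap, and Npas2 at 0.33, 0.25 and 0.54 and at 0.04, 0.01 and 0.09. Tef, Cry2 and Per3 passed in all 6 fits that left out 1 library. Per2, Ciart, Nr1d1 and Nr1d2 missed the threshold without BT replicate 1, with a highest adjusted p between 0.0613 and 0.131.

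**Figure D2:**
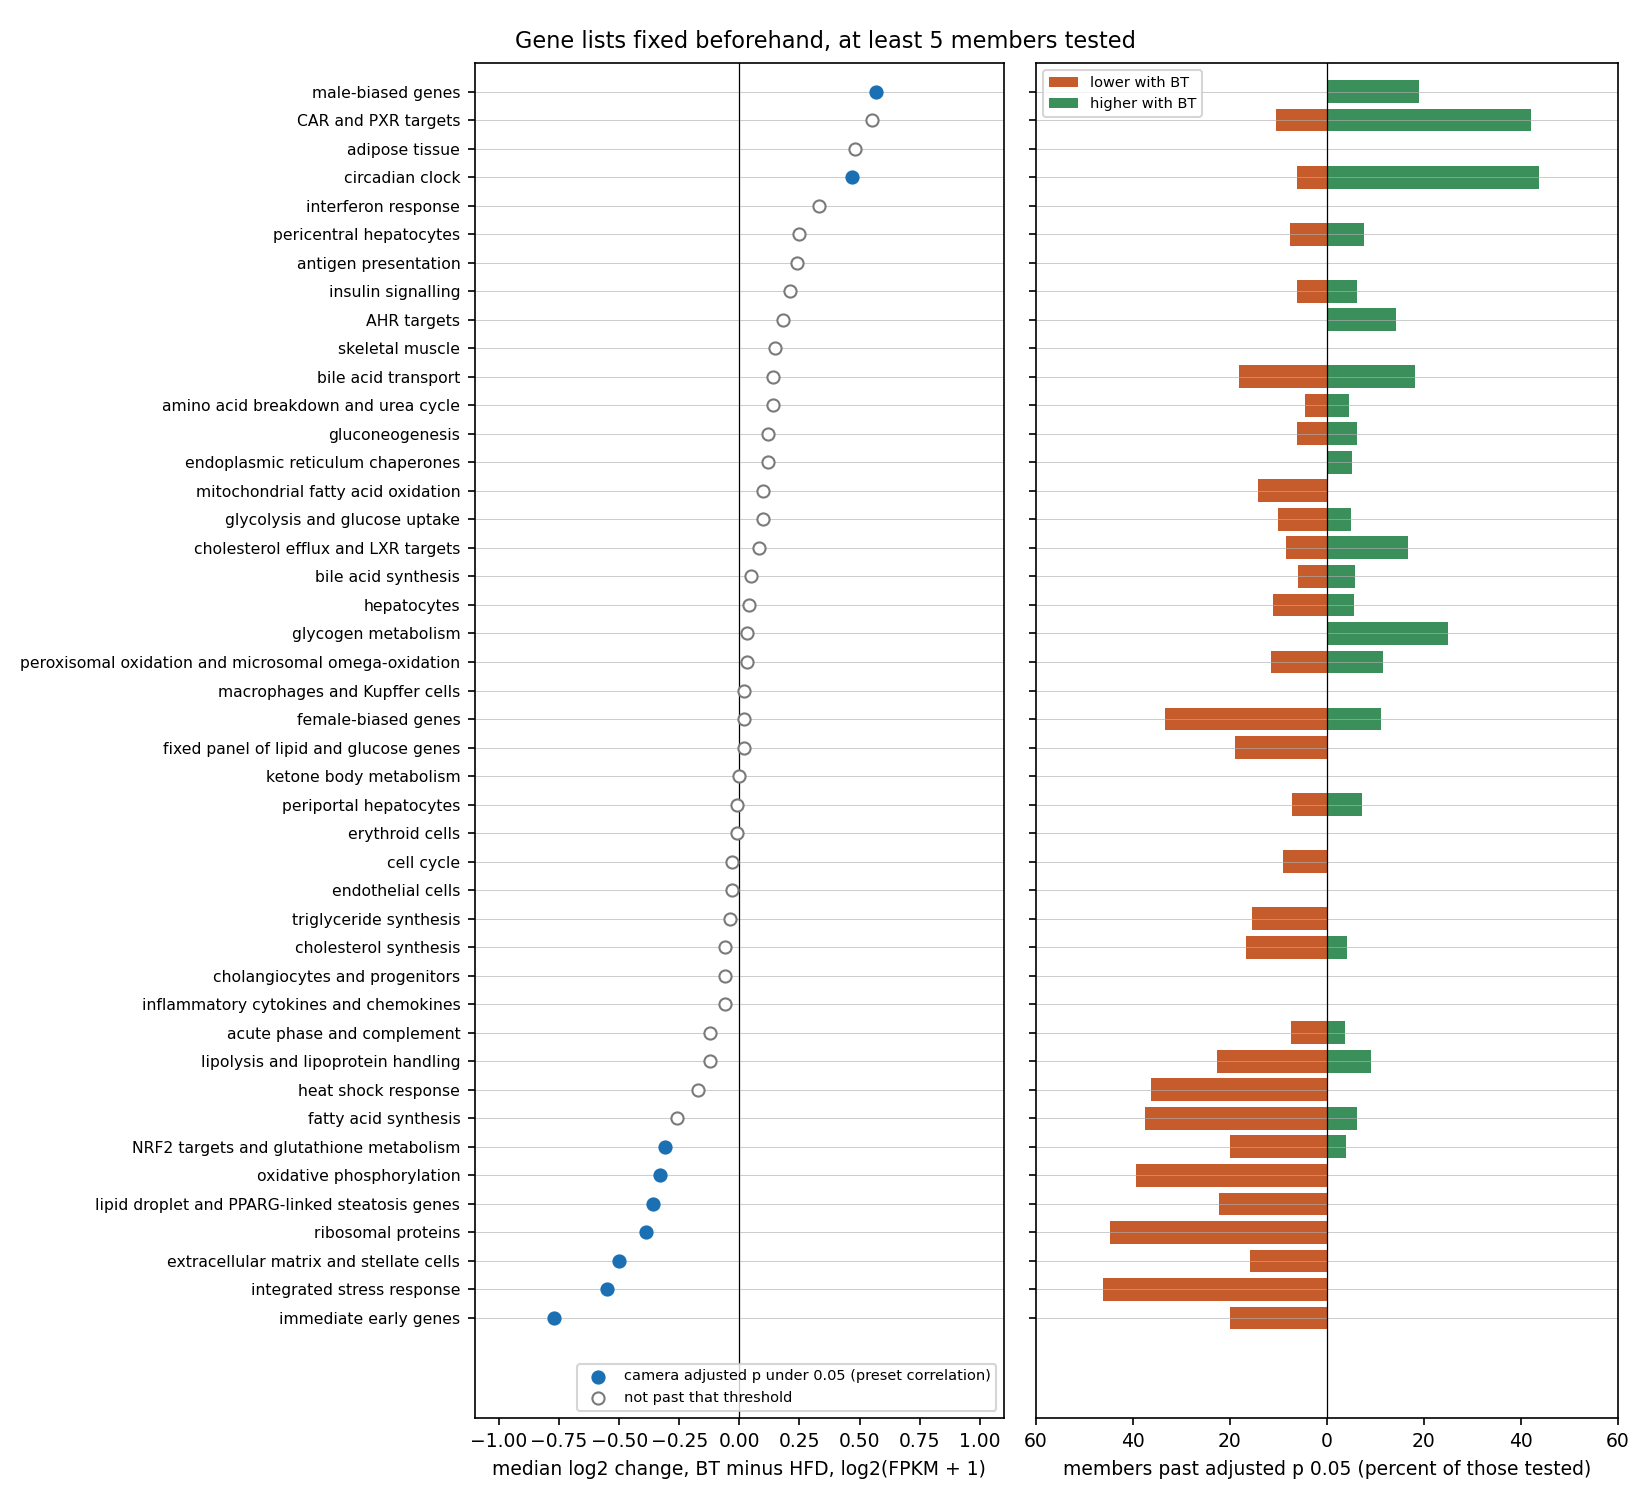
Left, median log2 change (BT minus HFD, log2(FPKM + 1)) of 44 gene lists with at least 5 members tested, filled where camera with a preset correlation passed. Right, the percent of tested members past adjusted p 0.05, lower to the left and higher to the right. Medians run from -0.77 (immediate early genes) to 0.57 (male-biased genes).

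Of 29 ribosomal protein genes 13 fell and none rose (19 and 0 adjusted over the list alone), with a median of -0.39. By camera adjusted p was 9.03e-10, and adjusted p = 0.667 with an estimated correlation. Rpl19 went from 368 ± 61.9 to 205 ± 7.17 FPKM (-0.83 ± 0.13, adjusted p = 0.0111), and Rplp1 and Rpl37 fell by 0.74 and 0.70. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Of 28 nuclear oxidative phosphorylation genes 11 fell and none rose (13 lower and 1 higher adjusted over the list alone), with a median of -0.33. This list passed camera at adjusted p = 1.16e-06, and adjusted p = 0.667 with an estimated correlation. Cox5a, a subunit of cytochrome c oxidase, fell from 213 ± 21.3 to 84.5 ± 5.04 FPKM (-1.32 ± 0.11, adjusted p = 0.00127), Cox6c by 0.92, Cox7a2 by 0.85 and Ndufa1, of complex I, by 0.91. Among the mitochondrially encoded genes mt-Atp6 fell by 0.70 (adjusted p = 0.0372) and the others did not pass. Change with BT also went with transcript length and GC content over all genes. The median was -0.10 in the decile of shortest transcripts and 0.20 in the longest, and 20.2% and 1.1% of these genes were lower. In the decile with the highest GC content the median was -0.05, with 13.9% lower. Libraries of the same diet also differed in this trend. In the longest transcripts HFD replicates 1, 2 and 3 deviated by 0, -0.14 and 0.13, and in the lowest GC decile by 0.03, -0.13 and 0.1. A trend of this kind thus also occurred between HFD libraries. These are single libraries, while the diet contrast compares means of 3, so the sizes cannot be set against each other directly. Cox5a, Cox6c and Cox7a2 passed in all 6 fits that left out 1 library. Rpl19, Rplp1, Rpl37, Ndufa1 and mt-Atp6 missed the threshold without BT replicate 1, with a highest adjusted p between 0.0569 and 0.142.

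**Figure D3:**
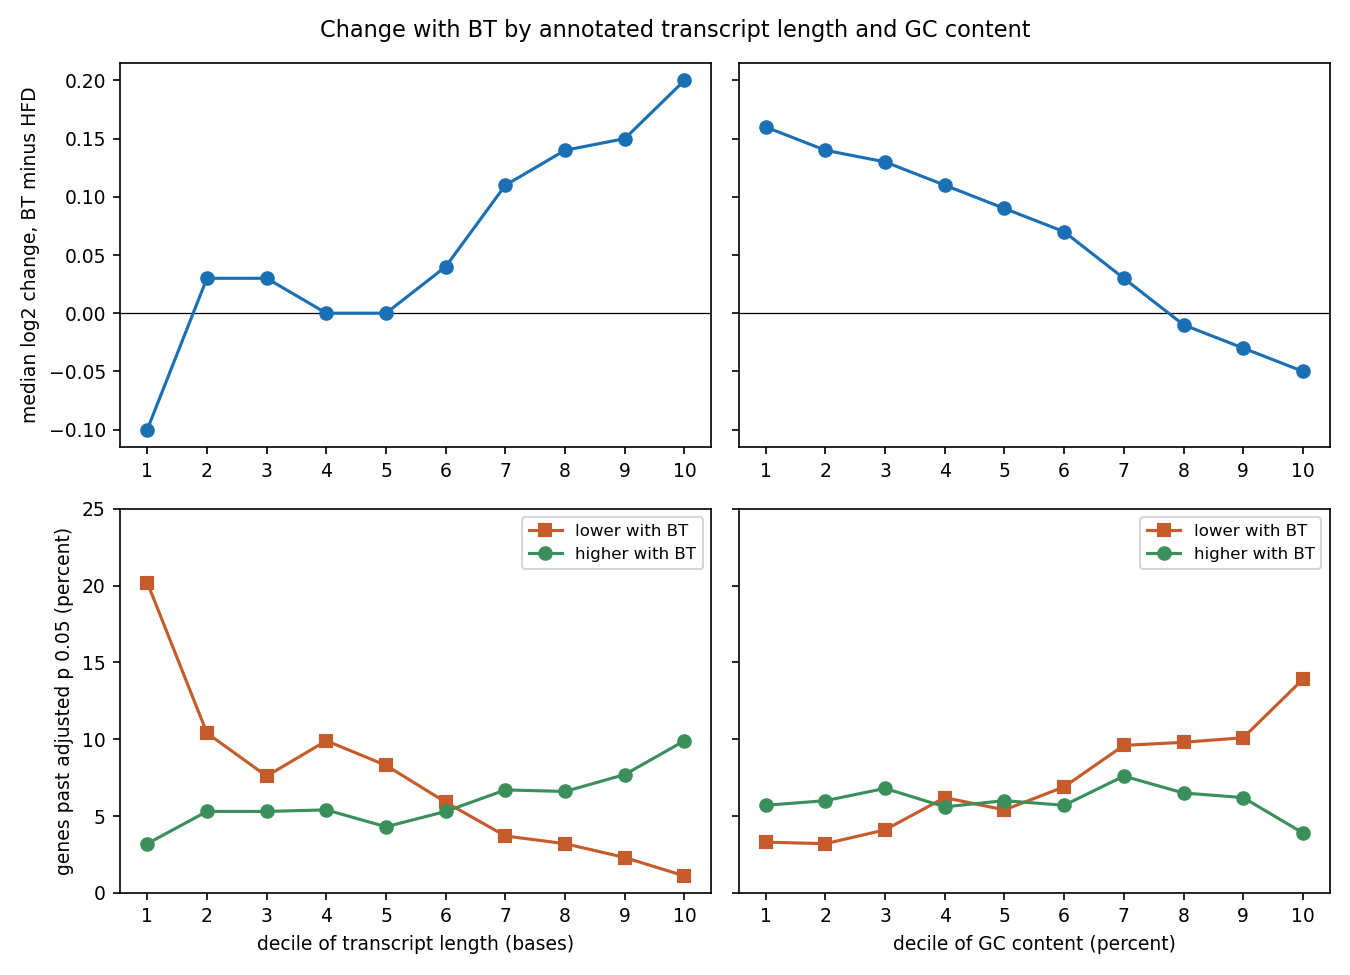
Top, median log2 change with BT by decile of annotated transcript length (left) and GC content (right), decile 1 lowest. Bottom, percent of genes in each decile that were lower (orange) or higher (green) at adjusted p 0.05, where the lower share goes from 20.2% in the shortest transcripts to 1.1% in the longest.

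Of 19 extracellular matrix and stellate cell genes 3 fell and none rose (6 and 0 adjusted over the list alone), all 19 were negative and the median was -0.50. Camera gave the list adjusted p = 1.16e-06, and adjusted p = 0.667 with an estimated correlation. Col3a1, a fibrillar collagen, went from 13.7 ± 6.24 to 4.49 ± 1.66 FPKM (-1.36 ± 0.34, adjusted p = 0.0354), Sparc fell by 0.99 and Tagln by 0.70, and Tgfb1 differed by -0.49 (adjusted p = 0.0511). An antisense gene model and others cover 67.9% of the exon bases of Tagln. These 3 missed the threshold without BT replicate 1, with a highest adjusted p between 0.0569 and 0.121. Of 20 macrophage and Kupffer cell genes none passed (median 0.02), with Cd5l at 0.43 (adjusted p = 0.0503) and Csf1r at 0.39 (adjusted p = 0.124). Of 16 endothelial genes none passed (median -0.03), with Stab1 at -0.48 (adjusted p = 0.0668) and Plvap at -0.40 (adjusted p = 0.113). No member passed among 25 interferon response, 14 antigen presentation and 11 cytokine and chemokine genes, also adjusted over each list alone, with medians of 0.33, 0.24 and -0.06. Gbp7 was at 15.63 FPKM in BT replicate 3 against 7.33 and 5.25 in the other BT libraries and 2.82 to 3.91 in HFD, and Tap1 was likewise highest there, at 40.95. The interferon response list passed camera without BT replicate 2 (median 0.46) and without HFD replicate 2 (median 0.40), while its median was 0.05 without BT replicate 3. With all libraries and an estimated correlation its adjusted p was 0.972. Tapbp differed by 0.40, Socs3 by 0.34 and Nfkb1 by 0.24. In acute phase and complement genes C3 rose by 0.69 ± 0.12 (adjusted p = 0.0129) while Orm1 and Orm3 fell, so that 1 of 27 was higher and 2 were lower (1 and 1 adjusted over the list alone). C3, Orm1 and Orm3 missed the threshold without BT replicate 1, with a highest adjusted p between 0.0582 and 0.177.

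Markers of less common cells were sparse. None passed, in all genes or adjusted over the list alone, among 2 T and natural killer cell genes (Zap70 0.09, Ccl5 -0.30), 3 B and plasma cell genes (Ighm -0.39, Cd79b 0.17), 4 neutrophil genes (Csf3r 0.33, Lcn2 -0.71) and 5 cholangiocyte and progenitor genes (Spp1 -0.58). The same held for 6 erythroid genes (Hba-a1 -0.50, Hba-a2 -0.54) and 10 skeletal muscle genes. The muscle genes Myh4 and Tnnt3 are listed at 0 in HFD replicate 1 and stood at 13.21 and 21.05 FPKM in HFD replicate 2. Of 5 adipose tissue genes none passed over all genes and 2 were higher adjusted over the list alone, with Lipe at 0.52 (adjusted p = 0.0512) and Car3 at 0.48 (adjusted p = 0.0764). The only pancreas gene above the filter, Cela1, fell by 0.67, and it missed the threshold without BT replicate 1 (adjusted p at most 0.0932). In the cell cycle 1 of 11 fell (1 adjusted over the list alone), Cdkn1a, an inhibitor of the cell cycle (-1.84 ± 0.31, adjusted p = 0.0134). Without BT replicate 1 it did not pass (adjusted p at most 0.0543 over the fits). Cdk1 differed by -0.60 (adjusted p = 0.0806).

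Male-biased liver genes had 4 of 21 members higher and none lower (6 and 0 adjusted over the list alone), with a median of 0.57. By camera adjusted p was 0.02, and adjusted p = 0.972 with an estimated correlation. The call was lost without HFD replicate 3 (median 0.34) and without BT replicate 1 (median 0.43). Cyp4a12a rose by 0.82 ± 0.18 (adjusted p = 0.0244), and Serpina1e and the complement genes C6 (0.90) and C8a (0.48) were also higher. Levels varied among the HFD libraries: Slco1a1 was at 42.86, 6.93 and 2.16 FPKM in replicates 1 to 3, against 41.07 to 55.65 with BT, Serpina1e at 109.91, 80.53 and 26.5, and C8a at 92.27, 93.54 and 69.18. Of 9 female-biased genes 3 fell and 1 rose (4 and 2 adjusted over the list alone), with Cyp17a1 at -1.44, Cyp2b9 at -2.04 and Slc22a27 at -1.12 as lower and Acot3 as higher. Among 18 hepatocyte genes 2 fell, Apoc3 (-0.98) and Ttr (-0.76), and 1 rose (2 and 3 adjusted over the list alone). Among pericentral genes Cyp1a2 rose and Lect2 fell by 0.56 (1 and 1 of 13, with 5 and 1 adjusted over the list alone). Among periportal genes Pigr rose by 0.73 and Sds fell (1 and 1 of 14, with 2 and 1 adjusted over the list alone). The genes named here as past the threshold missed it without BT replicate 1, with a highest adjusted p between 0.058 and 0.17.

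By camera with a preset correlation 9 of 47 lists passed, 7 lower and 2 higher. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.667. That test rests on the 4 residual degrees of freedom, so it had little power and does not show that correlation removed these signals. As the 2 tests differ, the description above gives counts of member genes. Other groupings of the same 6 libraries gave up to 22 lists by the preset correlation. They mix the diets and keep part of the diet contrast, so they do not measure chance. Over all genes tested 13.3% passed. Counts near that share, as in bile acid synthesis, gluconeogenesis and insulin signalling, show no change particular to the list. Beyond the 9 lists past camera, heat shock genes passed in 9 of 19 other settings, CAR and PXR targets in 5, fatty acid synthesis in 4 and interferon response and skeletal muscle in 2. Acute phase, amino acid breakdown, chaperone and pericentral genes passed in 1. Over these settings the median of matrix genes ran from -0.99 to -0.36, that of the integrated stress response from -0.80 to -0.33 and that of immediate early genes from -0.95 to -0.51. By fry, which asks whether members move on balance one way, 6 lists passed, 3 of them among the 9. The median was positive while camera ranked the list lower for mitochondrial fatty acid oxidation, peroxisomal oxidation, glycolysis, hepatocyte, female-biased, B cell and neutrophil genes and the fixed panel, and negative while camera ranked it higher for cytokines and chemokines. For hepatocyte genes the mean was 0.23 and for female-biased genes -0.50. The hepatocyte mean includes Alb, whose listing at 0 in HFD replicate 3 may be a failed estimate, so it says little about that list.

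Whether some named genes passed depended on the scaling. With quantile normalization 17 of them no longer passed, among them Apoa2 (adjusted p = 0.226), Fabp1 (adjusted p = 0.188), Eci1, Cyp8b1, Fads1 and G0s2. With the length and GC trend removed 25 of them no longer passed, among them Scd1, Fads1, Slc25a1, G0s2, Angptl8, Ces1g, Pdk4, Sds, Trib3, Cyp2c54, Cyp2c50, Cyp2c37, Nupr1, Ddit4, Klf2, Orm1, Cela1, C6 and C8a. With median-of-ratios scaling 20 did not, among them Serpina1e, Mlxipl, Stard4, G0s2, Angptl8, Ces1g, Got2, Akt1, Slco2b1, Cyp2c54, Cyp2c50, Cyp2c37, Alas1, C6 and C8a. On rescaling to TPM 25 did not, among them Scd1, Cyp8b1, Fads1, Me1, Acacb, Slc25a1, Agpat2, G0s2, Sds, Slc2a1, Trib3, Akt1, Ddit4, Bag3, Jun, Klf2, Orm1, Orm3, Cela1 and Slc22a27. Conversely, a replicate block brought 14 named genes past the threshold, among them Srebf1, Fasn, Cyp7a1, Slc16a1, Hsp90b1, Zfp36, Gbp7, Stab1, Plvap, Lipe, Car3 and Slco1a1. Slc16a1, Hsp90b1, Zfp36, Gbp7, Stab1, Plvap, Lipe, Car3, Slco1a1, Socs3, Tgfb1, Cd5l, Csf1r, Ighm, Spp1 and Cdk1 each passed in at least 1 further setting. A lost call is not a lost change. Over all settings Angptl8 stayed between -1.63 and -1, G0s2 between -1.4 and -0.84, C6 between 0.72 and 1.2 and Ces1g between 0.31 and 0.54.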

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

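Chosen after seeing the data were the removal of the length and GC trend, the restriction to annotated transcripts and the treatment of 2 zeros as missing; the other settings were fixed beforehand. All 1398 changed genes kept their direction in every setting that tested them. Without a filter on low values 545 genes passed, 200 higher and 345 lower, where 17095 genes were tested. Leaving out 1 library gave 173 to 1536 genes, 49 to 855 higher and 124 to 814 lower, and 8 to 14 gene lists; fewer libraries remain in these fits. The lowest count came without BT replicate 1 (173), followed by BT replicate 2 (324), BT replicate 3 (589) and HFD replicate 2 (621), and the list count was 14 without HFD replicate 1 and without HFD replicate 2. Camera with an estimated correlation gave 0 lists. All other settings gave 1171 to 1808 genes, and each kept all 9 lists. Rescaling to TPM moved the median of all genes to 0.154, against 0.07, and gave 614 higher and 557 lower genes. With the length and GC trend removed 1330 genes passed, 1063 of them among the 1398. Over all settings the named genes gave 608 losses and 59 gains of the threshold and no reversal. Skeletal muscle genes reversed without HFD replicate 1, at a median of -0.7, where Myh4 and Tnnt3 are listed at 0, and stood at 1.01 without HFD replicate 2, where both were highest, so 2 HFD libraries set this list. No other list reversed. The replicate numbers are shared by both groups, but no label says that they pair libraries. Deviations of same-numbered libraries correlated at 0.163, 0.097 and 0.147 across genes, against -0.134 to 0.009 for other pairs. Every library thus correlated best with its own number. The deviations are centred within each diet, so these values are tied to one another. They are a weak hint at most and do not show pairing. With a replicate block 1808 genes passed, 859 higher and 949 lower, and 9 lists. The depth, roughly estimated at 13.8 to 15.8 M fragments, limits genes near 1 FPKM most.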

Other observations

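Chosen only after the results were seen were the families by symbol stem, the test of non-hepatocyte markers, the test of clock phase and the matching on protein-coding transcripts, and the other tests were set beforehand. Gene families grouped by symbol stem extended the account of the translation and respiratory genes. Of 157 families with at least 8 members, 20 passed camera with a preset correlation, 16 lower and 4 higher, and no estimated correlation was run for them. Of 46 Rpl genes 29 were lower, of 43 Rps genes 20 were lower and 1 higher, and of the mitochondrial ribosomal genes 13 of 46 Mrpl and 11 of 30 Mrps were lower, with 1 Mrps gene higher. In the respiratory chain 12 of 14 Ndufa, 9 of 10 Ndufb, 3 of 8 Ndufs and 12 of 20 Cox genes were lower. The medians were -0.56 for Rpl, -0.45 for Rps, -0.73 for Ndufa, -0.57 for Ndufb, -0.38 for Ndufs and -0.76 for Cox. All stayed negative under the 3 other scalings and with the length and GC trend removed.

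The 4 families that ranked higher by that test were Usp (deubiquitinases, only 2 of 37 past the threshold), Ces (carboxylesterases, 3 of 12), Kmt (histone methyltransferases, 2 of 8) and Chd (chromatin remodellers, 3 of 9). Their medians were 0.24, 0.31, 0.36 and 0.51, and all stayed positive under the other scalings. Collagen genes (Col) had a median of -0.40 with 1 of 16 lower and 1 higher. The Atp family, with 14 of 54 lower and 2 higher, had a median of -0.05, which turned to 0.04 on rescaling to TPM. Among random lists matched on length, GC content and expression, a share of at least 0.05 was as low for 3 families: Atp (0.1232), Timm (0.0642) and Ndufs (0.0663).

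The real grouping gave 1398 changed genes in 1 of the 10 splits of the 6 libraries, and the highest other split gave 1. For higher and for lower genes likewise 1 split was as large, with at most 1 gene in the others. For gene lists the real grouping gave 9, the highest other split 22, and 8 of the 10 splits, the real one included, gave at least 9. With 10 splits no share under 0.05 can be reached. All the other splits hold libraries of both diets on each side. Part of the diet contrast thus stays in their difference, and the rest adds to their spread. They are not free of a diet effect, so they cannot show whether the gene counts or the preset-correlation list count exceed chance.

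The matching does not decide whether the length and GC trend is the whole cause of the lower oxidative phosphorylation genes, and the trend may account for a part. Their median of -0.33 lay at the lower bound of the central range of matched lists (-0.33). Random lists ignore the correlation between members, which was estimated at 0.319 for this list. For ribosomal protein genes the matching does not decide either, as the share depended on the transcripts and pool used (0.0271, 0.1216 or 0.0079). Among random lists matched on length, GC content and expression, a share of 0.0271 was as low as the ribosomal list (matched median -0.16 against -0.39) and 0.0255 as low as the oxidative phosphorylation list (-0.11 against -0.33), and with the trend removed both lists still passed camera with a preset correlation, at medians of -0.28 and -0.27. With lengths from protein-coding transcripts the shares were 0.1216 and 0.0376 in a pool that holds related families, and 0.0079 and 0.0042 without them. Compression of highly expressed genes is argued against only weakly, with shares of 0.002 and 0.0036 for lists matched on expression alone. These random lists ignore the correlation between members as well, and with an estimated correlation camera gave adjusted p = 0.667 for both. The diet and a difference between library sets, which follow the same split, both stay open.

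For stress, lipid droplet and matrix genes the length and GC trend is argued against as the whole cause: shares of matched lists as low were 1e-04 for the integrated stress response and for matrix genes, the smallest the 10000 lists can give, and 3e-04 for lipid droplet genes. Random lists ignore the correlation between members, and with an estimated correlation camera gave adjusted p = 0.667 for each; with the trend removed the medians were -0.55 for the stress response, -0.52 for matrix and -0.35 for lipid droplet genes. A lower share of all non-hepatocyte cells would lower endothelial and macrophage markers as much as matrix genes, but the matrix median lay lower by a difference of -0.47 (95% bootstrap interval over genes -0.82 to -0.36, 19 against 36 genes). Genes are not independent replicates, so that interval is too narrow. A change in stellate cells alone, handling of the tissue at collection (immediate early genes were low as well, at a median of -0.77, or -0.51 without HFD replicate 1), the diet and the library sets stay open.

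The clock genes may reflect a different time of day at tissue collection, a shift of the clock by the diet, or both. Length and GC content argue little, as a share of 1e-04 of matched lists, the smallest possible, was as high. For a different time of day, 1 clock gene past the threshold, Nr1d1, moved against the other 7, but these directions were known when the test was set and Nr1d1 passed in only 2 of the 6 fits that left out 1 library, so the count decides nothing. The labels used here give no collection time, so a different time of day stays open beside the diet and the library sets.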
